A study of Bacteroides fragilis 638R and Bacteroides finegoldii CL09T03C10 and Bacteroides ovatus ATCC 8483 with 20 samples.

How the data were processed

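RNA was sequenced from 5 wild-type Bacteroides strains with 4 libraries each. Per the labels' protocols, the cultures grew for 24 h at 37 °C in brain heart infusion with vitamin K and hemin at 5 µg/mL each, under 5% H2, 10% CO2 and 85% N2. RNA was extracted with TRIzol and columns, treated with DNase, and carried forward at 250 ng with integrity numbers above 8. Libraries were made with a stranded total RNA kit after depletion of ribosomal RNA, with a mean fragment of 396 bp. The submitters' processing notes name fastp, BWA and Subread. Genome builds, annotation, strand setting and treatment of reads with several matches are not given in the sources used here, and each of these can move the count of single genes, in particular of genes with near-identical copies.

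The authors deposited 1 table of raw gene counts per strain, with whole numbers for each library and locus tags as gene identifiers; the counts are not normalized and replicates are not pooled. Every row of the tables is a locus tag, so no row was removed. Columns were matched to samples by the number in the sample title, and the sample description names the table. Gene names, products and lengths are not in the sources used here. For this reason 4 planned results were not computed: DGR gene expression between strains, genes shared between strains, read shares of gene classes, and the rank of DGR genes within each transcriptome. The 21 gene lists fixed for them were not used. Only the planned comparison of transcriptome shape was computed, and the study's own question on DGR transcription is left unanswered here. Before the data were examined, the planned measures, their tests and the rule for named genes were fixed. For the most read genes, the rule asked for protein-coding genes, with at most 2 identifiers in a strain without gene names. Which rows encode proteins is not given, so the 2 rows with the highest mean CPM were taken instead. The runs of genes were singled out afterwards.

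Per library, CPM was computed from the deposited counts over all rows of the table. The planned measures were the share of reads in the 10 and in the 100 most read genes, the share of genes with at least 10 reads, and the mean Pearson correlation of log2(CPM + 1) with the other libraries of the strain. The number of genes holding 50% of the reads, the interquartile range of log2(CPM + 1), the share in the top 2% of genes and the share of genes holding 50% of the reads were added after the data were seen, as were the rules for genes under 1 CPM and for 4-fold differences, and all analyses of gene runs and of the spread between libraries other than the mean correlation. Strains were compared pair by pair with an exact two-sided permutation test of the difference of means (70 splits of 4 against 4, smallest p = 0.0286), adjusted by Benjamini and Hochberg over the 10 pairs of a measure. At least 6 pairs must reach the smallest p for any to pass, so a permutation test over all 5 strains (100000 resamples, added after the data were seen) is given beside measures with fewer. With 1 library left out of each strain the smallest p is 0.1, so those settings count strain pairs whose libraries do not overlap. Genes are not matched between strains, so no gene-level test between strains was made.

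Common dispersion was estimated with edgeR 4.0.16 in R 4.3.3, per strain, with TMM factors and genes kept by filterByExpr. Genes were called different between libraries where log2(CPM + 1), scaled by TMM, ranged by at least 2 and the mean was at least 50 reads; the pseudocount of 1 understates the range of low genes. Clustering along the row order was tested over 10000 row orders, the observed one included. The tables follow the authors' row order, and contig boundaries and coordinates are not in them. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

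The methods were tested on simulated data drawn from each strain's mean profile and library totals. With a coefficient of variation set to 0.15, edgeR gave 0.149 for B. fragilis, 0.148 for B. finegoldii and 0.149 for B. ovatus. It gave 0.150 for B. thetaiotaomicron and 0.148 for B. uniformis. In this order of strains 4409, 4224, 4914, 4873 and 3763 genes were simulated, and the estimate used those kept by filterByExpr. Of 100 genes per strain raised 8-fold in 1 library, 100% were called; of 100 raised 3-fold, 18% to 21% were called; 0 other genes were called at that spread, which is below the strains' own. In 100 simulations at each strain's own coefficient of variation, with genes drawn apart, the 4-fold rule called 16.01 genes on average (8 to 28) in B. fragilis, 8.81 (1 to 16) in B. finegoldii, 26.0 (18 to 36) in B. ovatus, 0.99 (0 to 5) in B. thetaiotaomicron and 0.25 (0 to 2) in B. uniformis. Alternatives covered scaling, count filter, pseudocount, thinning of every library to 21987747 reads, leaving out each replicate number, and the replicate number as a block.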

Results

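RNA-seq read counts were collected from 5 wild-type strains of Bacteroides, anaerobic bacteria of the human gut, with 4 libraries per strain and 20 in all. The strains were B. fragilis 638R, B. finegoldii CL09T03C10, B. ovatus ATCC 8483, B. thetaiotaomicron VPI-5482 and B. uniformis ATCC 8492. Each was cultured for 24 h at 37 °C in brain heart infusion, a rich medium, without oxygen. The strains differ in the activity of their diversity-generating retroelements (DGRs), elements in which a reverse transcriptase copies a template repeat with errors at adenines and the copy replaces part of a target gene. The design asks whether that activity is set at the level of transcription. The count tables name genes only by locus tag, and no annotation was used here, so the DGR reverse transcriptase, accessory and target genes were not analysed here. The comparisons below concern how each strain distributed its reads over its own genes.

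The tables held 4409 genes for B. fragilis, 4224 for B. finegoldii, 4914 for B. ovatus, 4873 for B. thetaiotaomicron and 3763 for B. uniformis. Total reads per library ranged from 21.99 to 45.9 M. At these depths a count of 0 allows at most 3 reads, or 0.0654 to 0.136 by library in CPM (counts scaled to the library total), for counting error only. Between 9 and 107 genes per library had no read. Within a strain, Pearson's r of log2(CPM + 1) across genes lay between 0.964 and 0.997, and genes are not independent replicates in such a correlation. The chi-square statistic per degree of freedom between libraries of 1 strain was 53.0 or more, so no library repeated another within sampling noise. The labels do not say whether the 4 libraries of a strain came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

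The first comparison asked how far each transcriptome was concentrated in a few genes. By shares of a fixed number of genes, B. finegoldii, B. uniformis and B. fragilis put more reads into their most read genes than B. ovatus and B. thetaiotaomicron. With gene number allowed for, B. fragilis overlapped B. ovatus and B. thetaiotaomicron, as given below. The 10 most read genes took 18.9% ± 2.47 of reads in B. finegoldii (SD, n = 4, as for all values of this kind), 16.4% ± 0.879 in B. uniformis and 15.98% ± 2.08 in B. fragilis. They took 11.9% ± 0.478 in B. ovatus and 10.6% ± 0.420 in B. thetaiotaomicron. Each of the first 3 strains exceeded each of the last 2, and B. ovatus exceeded B. thetaiotaomicron, which makes 7 of 10 strain pairs (exact two-sided permutation test of 4 against 4 libraries, p = 0.0286, the smallest it can give; Benjamini-Hochberg adjusted p = 0.0408 over the 10 pairs). B. finegoldii against B. fragilis, B. finegoldii against B. uniformis and B. fragilis against B. uniformis did not pass, with adjusted p from 0.127 to 0.743 in the same exact test. That test takes no account of the replicate number. The share in libraries 1 to 4 was 22.1%, 19.1%, 18.3% and 16.2% in B. finegoldii against 17.0%, 18.1%, 15.7% and 13.2% in B. fragilis. B. finegoldii was thus higher at each number, also for the 100 most read genes. The pairs with B. uniformis went both ways. Strain pairs were not tested by number. Without the most read gene of each strain, 6 pairs passed. The shares were then 13.2% ± 0.281 in B. finegoldii, 12.6% ± 1.72 in B. fragilis and 12.5% ± 0.718 in B. uniformis. They were 10.2% ± 0.482 in B. ovatus and 8.58% ± 0.265 in B. thetaiotaomicron. The lead of B. finegoldii and its spread between libraries thus rested largely on its most read gene.

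The 100 most read genes of B. uniformis took 52.4% ± 2.41 of its reads, more than in each of the other 4 strains. The share was 45.8% ± 2.20 in B. finegoldii, 43.1% ± 2.74 in B. fragilis, 38.2% ± 0.654 in B. ovatus and 37.7% ± 0.691 in B. thetaiotaomicron. By this measure 8 of 10 pairs differed (exact permutation test, adjusted p = 0.0357); B. fragilis against B. finegoldii and B. ovatus against B. thetaiotaomicron did not pass. The strains differ in gene number, and shares of a fixed number of genes depend on it. With the top 2% of each strain's genes in place of the top 100, the shares were 46.6% ± 2.25 in B. uniformis, 43.1% ± 2.23 in B. finegoldii, 41.0% ± 2.72 in B. fragilis, 37.8% ± 0.655 in B. ovatus and 37.1% ± 0.679 in B. thetaiotaomicron. The order was kept. A permutation test over the 5 strains gave p = 0.00013, while no pair passed after adjustment (smallest adjusted p = 0.0714 in the exact permutation test). The libraries of 4 pairs did not overlap: B. uniformis and B. finegoldii, each against B. ovatus and B. thetaiotaomicron. These pairs had the smallest p the test can give, which passes adjustment only when at least 6 of the 10 pairs reach it. B. fragilis overlapped B. ovatus and B. thetaiotaomicron (unadjusted p = 0.0857 and 0.0571, exact permutation test).

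The number of genes that together held 50% of the reads was 90.3 ± 11.1 in B. uniformis, 130 ± 16.2 in B. finegoldii, 151 ± 23.4 in B. fragilis, 193 ± 7.04 in B. ovatus and 194 ± 6.93 in B. thetaiotaomicron. By this count the same 8 pairs differed (adjusted p = 0.0357, exact permutation test), but it too depends on gene number. As a share of each strain's genes the means were 2.40% ± 0.296, 3.08% ± 0.384, 3.42% ± 0.531, 3.93% ± 0.143 and 3.98% ± 0.142 in the same order of strains. The permutation test over the 5 strains gave p = 0.00023, the libraries of 5 pairs did not overlap, and no pair passed after adjustment (smallest adjusted p = 0.0571, exact permutation test; 5 pairs with an unadjusted p under 0.05). As a share, B. fragilis again overlapped B. ovatus and B. thetaiotaomicron (unadjusted p = 0.143 against each, exact permutation test). In number, B. ovatus and B. thetaiotaomicron differed by 0.75 genes, within the spread of either strain. Without the most read gene of each strain, 6 pairs passed by number. The interquartile range of log2(CPM + 1) over genes was 3.72 ± 0.06 in B. uniformis and 4.00 ± 0.02 in B. fragilis, against 4.37 ± 0.04 in B. thetaiotaomicron, 4.51 ± 0.05 in B. finegoldii and 4.59 ± 0.21 in B. ovatus. B. ovatus did not pass against B. finegoldii or B. thetaiotaomicron, and the other 8 pairs did (adjusted p = 0.0357, exact permutation test).

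**Figure D1:**
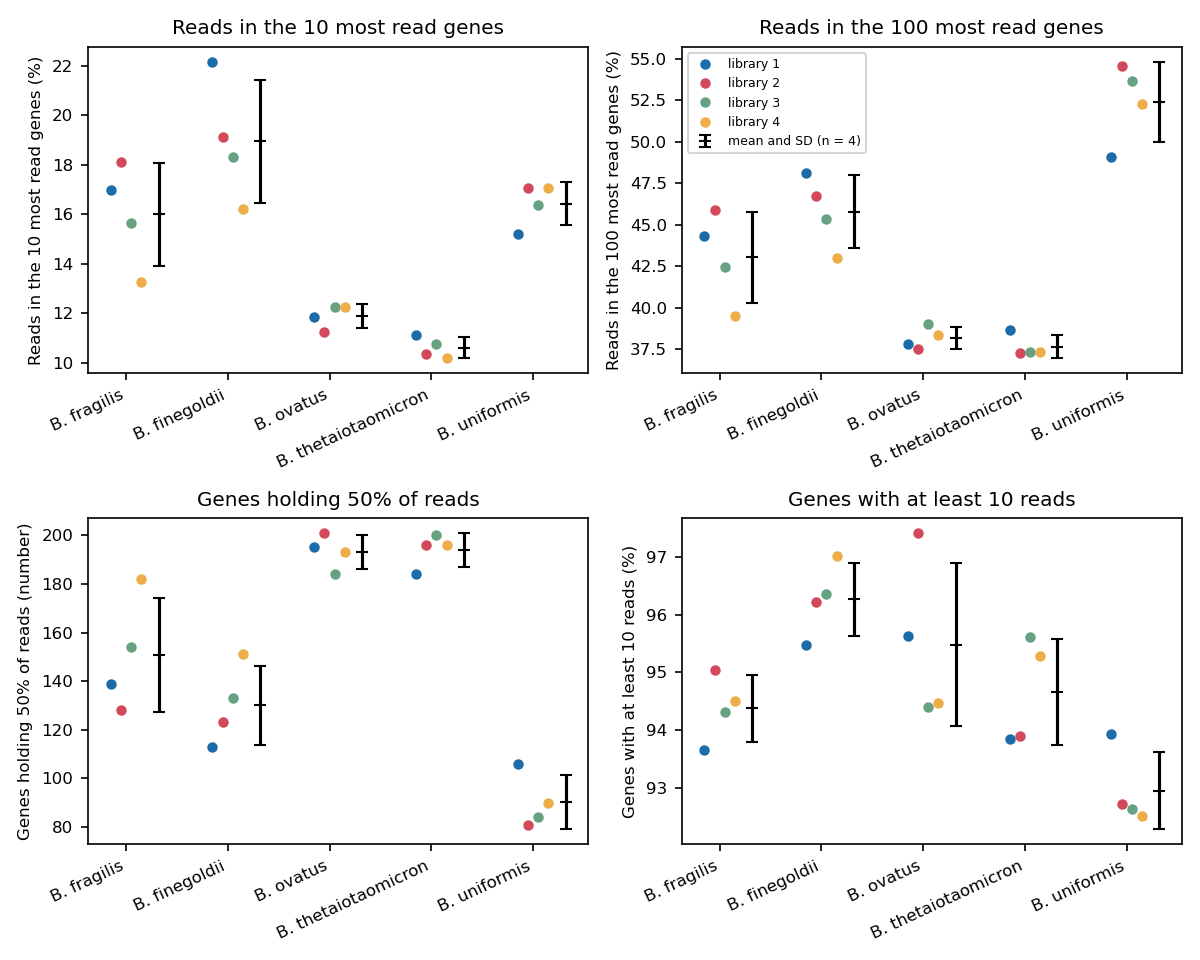
Read distribution per strain: the vertical axes give the share of reads in the 10 and the 100 most read genes (%), the number of genes holding 50% of reads and the share of genes with at least 10 reads (%), with axes that do not start at 0. Coloured points are the libraries with replicate numbers 1 to 4, and black bars are the mean and SD (n = 4); the 100 most read genes took 52.4% of reads in B. uniformis and 37.7% in B. thetaiotaomicron.

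A single gene led the counts in each strain. In B. finegoldii, HMPREF1057_RS21455 took 7.53% ± 2.57 of reads and was 4.19 times as high as the next gene, HMPREF1057_RS00265 at 1.80% ± 0.497. Its share differed more between libraries than that of any other leading gene, with 10.7% in library 1, 7.86% in library 2, 6.998% in library 3 and 4.51% in library 4. In B. uniformis, NQ510_RS17790 took 5.41% ± 0.270, followed by NQ510_RS06235 at 2.04% ± 0.159. In B. fragilis, BF638R_RS22525 took 4.69% ± 0.542, followed by BF638R_RS21115 at 1.55% ± 0.229. In B. thetaiotaomicron, BT_RS22200 took 2.90% ± 0.384, followed by BT_RS13860 at 1.35% ± 0.0923. In these 4 strains the same gene was the most read in 4 of 4 libraries. In B. ovatus, Bovatus_RS22750 took 2.63% ± 0.900 and was the most read in 3 libraries, while Bovatus_RS24130, at 1.71% ± 0.545 on average, was the most read in library 1. The tables do not pair these locus tags with gene names, and they do not say whether a leading gene encodes a protein.

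Nearly all genes of each strain held reads under the single culture condition. Whether counts as low as 10 reads reflect transcription of the gene was not tested. At least 10 reads fell on 96.3% ± 0.631 of genes in B. finegoldii, 95.5% ± 1.41 in B. ovatus, 94.7% ± 0.917 in B. thetaiotaomicron, 94.4% ± 0.572 in B. fragilis and 93.0% ± 0.666 in B. uniformis. A permutation test over the 5 strains gave p = 0.00119. No single strain pair passed after adjustment (smallest adjusted p = 0.0952, exact permutation test), and 3 pairs had an unadjusted p under 0.05, where 6 at the smallest p are needed. Thinned to 1 depth, the means were 95.0%, 94.2%, 93.1%, 93.0% and 92.6% in the same order. B. uniformis had 57 genes with no read in any library, or 1.51% of its genes, against 8, 2, 4 and 8 genes in B. fragilis, B. finegoldii, B. ovatus and B. thetaiotaomicron. That difference was not tested, since the 4 libraries of a strain share 1 gene table. Of the 57 genes, 37 lay in a single stretch of 40 rows, NQ510_RS07420 to NQ510_RS07615, described below.

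Genes with a mean under 1 CPM were grouped along the row order of the tables in every strain; coordinates were not used, so neighbouring rows are not shown to be neighbours on the genome. They numbered 450 in B. fragilis (10.2% of genes), 343 in B. finegoldii (8.12%), 422 in B. ovatus (8.59%), 513 in B. thetaiotaomicron (10.5%) and 365 in B. uniformis (9.70%). Between 67.9% of these genes in B. finegoldii and 82.2% in B. uniformis stood beside another in that order. Shuffled row orders gave means of 53.2 to 102 such genes per strain, where 233 to 392 were observed (one-sided permutation test over 10000 row orders, the observed one included, p = 0.0001 in each strain, the smallest it can give; genes are not independent replicates). The longest stretch of each strain is named here after its values were seen. In B. uniformis, 40 genes in a row from NQ510_RS07420 to NQ510_RS07615 held 64 reads over the 4 libraries, and 37 of them had none. In B. fragilis, 34 genes from BF638R_RS24055 to BF638R_RS25375 held 349 reads. Their tag numbers span far more than those of the other stretches, so this stretch in particular is not shown to be 1 region of the genome. In B. ovatus, 27 genes from Bovatus_RS20260 to Bovatus_RS20385 held 1029 reads. In B. thetaiotaomicron, 22 genes from BT_RS00400 to BT_RS00510 held 453 reads. In B. finegoldii, the longest stretch had 8 genes, from HMPREF1057_RS07255 to HMPREF1057_RS07225, with 190 reads. No shuffle in any strain gave a stretch of more than 7 genes.

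The second comparison asked how far the 4 libraries of a strain differed from each other. The common biological coefficient of variation from edgeR was 0.299 in B. ovatus, 0.288 in B. fragilis, 0.276 in B. finegoldii, 0.239 in B. thetaiotaomicron and 0.223 in B. uniformis; differences between strains were not tested. The mean correlation of a library with the others of its strain was 0.981 ± 0.00515 in B. fragilis, 0.982 ± 0.00167 in B. ovatus, 0.984 ± 0.00377 in B. finegoldii, 0.988 ± 0.00157 in B. thetaiotaomicron and 0.989 ± 0.00296 in B. uniformis. A permutation test over the 5 strains gave p = 0.0179. No single strain pair passed after adjustment (smallest adjusted p = 0.143, exact permutation test), and 1 pair, B. ovatus against B. thetaiotaomicron, had an unadjusted p under 0.05. These correlations share libraries and are not independent values.

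**Figure D2:**
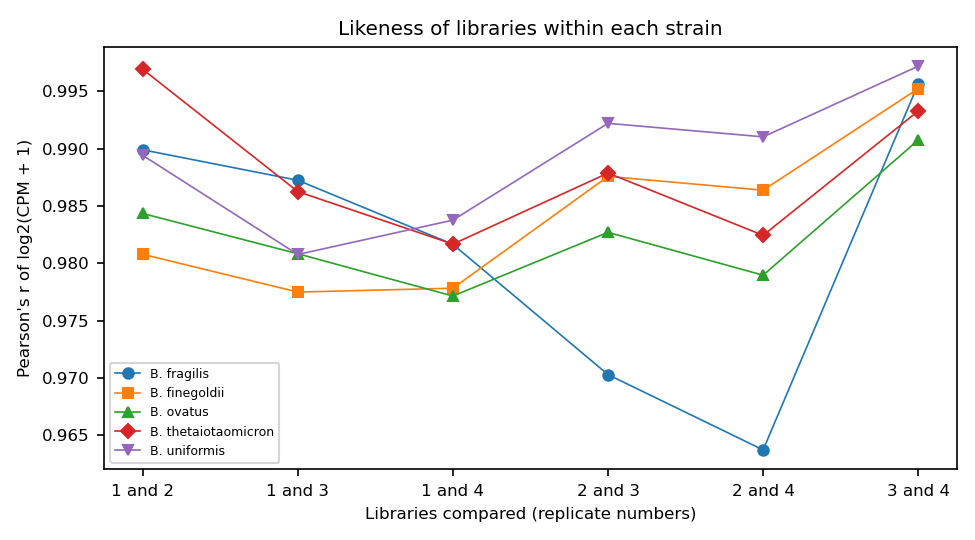
Pearson's r of log2(CPM + 1) across genes for each of the 6 pairs of libraries in each strain, by replicate number; the vertical axis does not start at 0. Libraries 3 and 4 had the highest r in 4 of 5 strains.

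Genes whose highest and lowest library differed at least 4-fold on the scale of log2(CPM + 1), after TMM scaling and with a mean of at least 50 reads, numbered 120 in B. fragilis (3.09% of genes tested), 105 in B. ovatus (2.40%), 62 in B. finegoldii (1.66%), 45 in B. thetaiotaomicron (1.06%) and 33 in B. uniformis (1.00%). Simulated libraries with each strain's own common coefficient of variation held 16.01, 26.0, 8.81, 0.99 and 0.25 such genes on average, in the same order of strains. The simulation gave all genes of a strain the same coefficient. It therefore does not show how many such genes arise where the spread between libraries differs from gene to gene. A range over fewer libraries can hardly grow, so leaving out 1 library lowers these counts in any case. The largest falls are given here. In B. fragilis the count was 33 without library 2 and 72 without library 4, in B. finegoldii 28 without library 1, and in B. ovatus 64 without library 2. In B. thetaiotaomicron it was 22 without library 4, and in B. uniformis 3 without library 1 and 8 without library 3. Without the libraries not named here the counts stayed higher, up to 111 in B. fragilis and 31 in B. uniformis.

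These genes also lay in neighbouring rows. Of the 365 genes over the 5 strains, 234 stood beside another in row order. The share was 75.6% in B. thetaiotaomicron, 70.5% in B. ovatus, 66.7% in B. uniformis, 65.0% in B. fragilis and 41.9% in B. finegoldii (one-sided permutation test over 10000 row orders, the observed one included, p = 0.0001 in each strain, the smallest it can give). There were 37 runs of 3 or more genes in neighbouring rows, 12 of them in B. ovatus, 10 in B. fragilis, 6 in B. thetaiotaomicron, 6 in B. uniformis and 3 in B. finegoldii. The longest run of each strain is named here after its values were seen, with mean TMM-scaled CPM over its genes. In B. finegoldii, 10 genes from HMPREF1057_RS17315 to HMPREF1057_RS17270 stood at 5.50 and 8.27 in libraries 1 and 2 and at 48.2 and 55.7 in libraries 3 and 4. In B. ovatus, 9 genes from Bovatus_RS02815 to Bovatus_RS02855 stood at 250.4 in library 4 against 50.0, 36.5 and 28.6 in libraries 1, 2 and 3. In B. fragilis, 8 genes from BF638R_RS07545 to BF638R_RS07585 stood at 147 and 68.3 in libraries 1 and 2 and at 356 and 440 in libraries 3 and 4. In B. uniformis, 6 genes from NQ510_RS02070 to NQ510_RS02095 stood at 70.9 in library 1 against 21.3, 13.9 and 17.1 in the others. In B. thetaiotaomicron, 5 genes from BT_RS07165 to BT_RS07185 stood at 312 and 156 in libraries 1 and 2 and at 34.5 and 31.8 in libraries 3 and 4. The widest difference was in B. ovatus, where 7 genes from Bovatus_RS06115 to Bovatus_RS06145 stood at 161 in library 1 and at 6.80 in library 4.

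**Figure D3:**
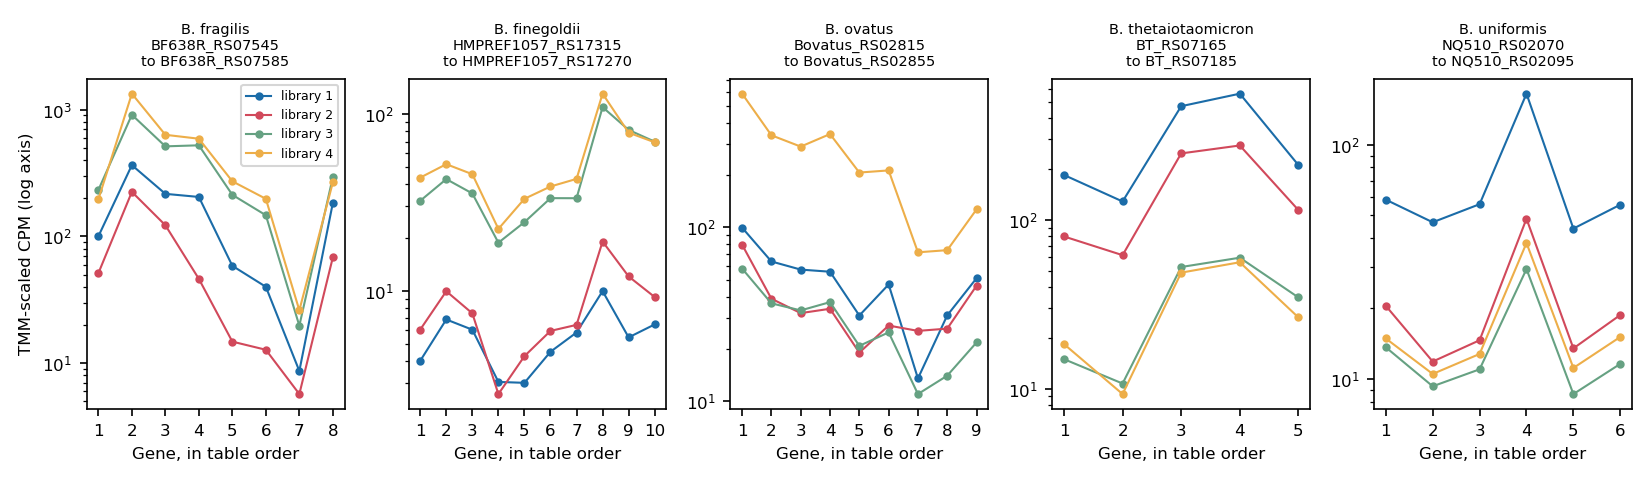
The longest run of genes in neighbouring rows that differed at least 4-fold between libraries, in each strain: the horizontal axis gives the genes in table order, the vertical axis TMM-scaled CPM on a log scale, and each line is 1 library. In B. finegoldii the 10 genes had means of 5.50 and 8.27 in libraries 1 and 2 and of 48.2 and 55.7 in libraries 3 and 4.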

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

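Of 50 groups of 4 libraries tested for a library far from the other 3 (Dixon's ratio of the gap to the nearest value over the whole range, past its 5% limit for 4 values), 8 were marked, where chance gives about 2.5. Several of the measures overlap, so the 8 are not independent, and the set of measures was chosen after the data were seen.

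Total reads stood apart in 3 strains. Library 2 of B. fragilis had 45.9 M reads against 28.1 to 31.0 M in the others, library 2 of B. ovatus had 45.0 M against 29.9 to 30.3 M, and library 3 of B. thetaiotaomicron had 43.6 M against 30.7 to 32.3 M. In B. thetaiotaomicron, library 1 had 38.7% of its reads in the 100 most read genes against 37.3% to 37.4% in the others, and 38.2% in the top 2% of genes against 36.7% to 36.9%. The gene BT_RS13860 took 1.48% of reads in library 3 of that strain and 1.29% to 1.32% in the others. In B. uniformis, library 1 had at least 10 reads on 93.9% of genes against 92.5% to 92.7%, and its mean correlation with the other libraries was 0.985 against 0.990 to 0.991.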

How the results depend on the processing

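The top 2% of genes, the runs without the most read gene, the replicate block, the share of genes holding 50% of the reads and all alternatives for genes that differ 4-fold between libraries, the coefficient of variation and genes under 1 CPM were chosen only after the result was seen. Of the planned results, DGR gene expression, shared genes, gene class shares and ranks of DGR genes were not run, with all their alternatives, because they need gene names or lengths. Thinning all libraries to 1 depth left the number of strain pairs past the threshold unchanged for each of the 4 planned and 3 added measures. With the top 2% of genes in place of the top 100, 0 pairs passed where 8 had; 4 pairs still did not overlap, fewer than the 6 that adjustment needs, and the permutation p over the 5 strains was 0.00013 (0.00014 with the replicate block). For genes holding 50% of the reads, taken as a share of the strain's genes, 0 pairs passed where 8 had by number; 5 did not overlap, and that p was 0.00023 (0.00016 with the block). Leaving out 1 replicate number gave 7 to 9 pairs with no overlap for the 10 most read genes (7 with all libraries). It gave 8 to 9 for the 100 most read (8) and 3 to 6 for genes with at least 10 reads (3). These measures are values of single libraries, so leaving libraries out cannot create an overlap. Their counts could not fall, and this setting is no check on them. The 6 arose without replicate 1. For the mean correlation, which was computed anew, 0 to 7 pairs did not overlap (1 with all libraries). The 7 arose without replicate 1, the 0 without replicate 2, and the cause was not tested. The exact test of a strain pair cannot pass with 3 against 3 libraries (smallest p 0.1). With the replicate number as a block, strain labels were permuted within a number (100000 resamples): the permutation p over the 5 strains was 9e-05 for the 10 most read genes (1e-05 without the block, the smallest it can give), 1e-05 for the 100 most read, 0.00566 for genes with at least 10 reads (0.00119 without) and 0.0214 for the mean correlation (0.0179 without). The p over the 5 strains thus stayed under 0.05, but the pair calls were not run with the block, since 4 pairs of libraries allow 16 sign swaps and no p under 0.125. The labels do not say that a number marks a shared day, and genes are not matched between strains, so whether the numbers pair the libraries gene by gene was not testable. Counts of genes that differ 4-fold between libraries moved with the filter: with a mean of at least 500 reads they fell to 40 in B. finegoldii and 18 in B. uniformis, since fewer genes were tested. With a pseudocount of 0.1 CPM they rose to 151 in B. ovatus, 130 in B. fragilis and 89 in B. finegoldii, which put B. ovatus above B. fragilis. They also rose to 61 in B. thetaiotaomicron and 47 in B. uniformis. Without 1 library, which leaves fewer samples for a range, they ranged from 33 to 111 in B. fragilis, 28 to 49 in B. finegoldii, 64 to 89 in B. ovatus, 22 to 40 in B. thetaiotaomicron and 3 to 31 in B. uniformis. The coefficient of variation then ranged from 0.228 to 0.316, 0.217 to 0.298, 0.286 to 0.313, 0.214 to 0.249 and 0.168 to 0.240 in the same order, and the cause was not tested. Counts of genes under 1 CPM stayed within 1.5 times under TMM scaling, thinning and each left-out library. Depth limits the genes near 0: thinning lowered the share with at least 10 reads in every strain.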

Other observations

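The tests of this part were chosen only after the result was seen, and the profiles of the gene runs had been looked at before the tests on them were written.

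Mean read levels of genes in neighbouring rows were correlated in all 5 strains, with no correction for gene length. Pearson's r of mean log2(CPM + 1) between a gene and the next in row order was 0.611 in B. fragilis, 0.655 in B. thetaiotaomicron, 0.662 in B. ovatus, 0.663 in B. finegoldii and 0.664 in B. uniformis. It fell to 0.294, 0.304, 0.297, 0.340 and 0.323 in these strains at 5 rows apart, and lay between -0.0132 and 0.0619 at 50 rows apart. Deviations of single libraries from the strain mean also ran together between neighbours, with r of 0.560 in B. fragilis, 0.545 in B. thetaiotaomicron, 0.559 in B. ovatus, 0.438 in B. finegoldii and 0.506 in B. uniformis. With shuffled rows the r between neighbours stayed between -0.0482 and 0.0318 for levels and between -0.0163 and 0.0168 for deviations. These correlations are across genes, which are not independent replicates.

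The libraries of the 5 strains lay at like distances from each other when ordered by replicate number. Libraries 3 and 4 were the closest in 4 of 5 strains, with r of log2(CPM + 1) of 0.996 in B. fragilis, 0.995 in B. finegoldii, 0.991 in B. ovatus and 0.997 in B. uniformis; in B. thetaiotaomicron libraries 1 and 2 were closest at 0.997, and 3 and 4 stood at 0.993. The mean Spearman's rho of the 6 distances between strains was 0.55, and over all 331776 relabellings of the numbers within strains the exact p was 0.00219, which argues against a chance match. The exact p over relabellings was 0.00219 after thinning to 1 depth and 0.00219 without the 100 most read genes of each strain. On genes of at least 500 reads it was 0.00174. These values argue against counting noise, also from unequal depth, and against a few abundant genes. Thinning equalizes only the number of reads, so differences of preparation that go with depth cannot be told apart. Shared handling of same-numbered cultures or libraries (day, inoculum or preparation order) may account for the likeness by number. It cannot be told apart from other causes because the labels give no batch. No biological explanation was tested, since the libraries of a strain carry the same labels.

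The runs of genes in neighbouring rows that differed between libraries of 1 strain invite several readings. Placement of each gene apart from its neighbours is argued against by a largest shuffle p of 0.0001 over the strains, and counting noise, drawn for each gene apart, by neighbours of these genes going the same way across libraries in 100% of pairs in each strain (with 1 pair per run, since pairs within a run share genes, 6 of 6 in B. uniformis, exact binomial p = 0.0313, the largest over the strains). Over all genes, deviations of single libraries also ran together between adjacent rows, with r of 0.438 to 0.560. Shuffling breaks that likeness as well, so neither test sets these runs apart from the likeness of neighbours in general. A shift of the whole transcriptome cannot be told apart from other readings. In 28 of the 37 runs every gene followed the first principal component of the strain's other genes (r2 of 0.5 or more). So did 24.3 on average (20 to 29 in 95% of 1000 draws) of 37 windows of like length from neighbouring rows that ranged 2-fold to 4-fold. The genes of these windows were among those the component was computed from, and the genes of the runs were not. This can raise the number for the windows, so the comparison does not decide the question. In 5 runs, 4 in B. ovatus and 1 in B. thetaiotaomicron, no gene followed the first component. Whether these runs follow a weaker shared shift or change on their own cannot be told apart. The first component held 54.05% of the variance in B. ovatus and 74.2% in B. thetaiotaomicron, and further components were not tested. Switching of single loci in 1 library cannot be told apart from the other readings either. A single library stood apart in 1 of 37 runs, Bovatus_RS07335 to Bovatus_RS07355 at 57.4 CPM in library 2 against 6.84 to 9.56, but in 5 runs with a slightly lower cut on the ratio of gap to range (0.8), on the other side of the bound of 1 in 10, and invertible regions were not searched for.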
